A study of Mus musculus with 15 samples.

How the data were processed

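Gene expression was measured in laser-microdissected tissue of the CA3 field of the mouse hippocampus at birth, in wild-type (WT) mice and in mice lacking doublecortin (Dcx KO). The labels place 15 arrays in 3 groups of 5, which are the inner CA3 layer of the KO, the outer CA3 layer of the KO and the CA3 layer of WT. Both KO layers came from the same 5 animals, so the 15 arrays stand for 10 animals. Per the labels' protocols, RNA of the dissected material was amplified, labelled with biotin and hybridised to Illumina whole-genome bead arrays.

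The deposited log2 signals came in 2 copies, which were equal when rounded to 7 decimals for the 25697 entries that both hold. Although the name of the first copy calls the values normalized, medians and spreads differed between arrays and the lowest values lay at the level of the control entries. The log2 signals were therefore treated as signals to which the authors had applied neither background subtraction nor normalization between arrays. A further deposited table, whose name calls it not normalized, held a score for each entry and array. Tested on the values, each score was the log2 signal minus the median of the array, divided by the SD of the array. On 8 arrays, those of KO animals 1 to 4, the authors had added a shift for each entry. The shift of the inner arrays was a straight-line function, of slope 0.588, of the difference between outer array 5 and the mean of outer arrays 1 to 4, and the shift of the outer arrays was one, of slope 0.738, of the matching inner difference (r = 1 for both, across entries). The other 7 arrays, KO animal 5 and the 5 WT arrays, carried no shift. The shift was read here as the authors' correction for an array batch, and the 2 sets of arrays are called the shifted and the unshifted arrays. The labels name no batch. Per the submitters' processing notes limma was used, in a role and version not given in the sources used here, and neither are the bead summary, the background correction and the annotation build.

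Of 26821 entries, 25697 carried a probe and 1124 did not. Of the latter, 1114 lay at background and served as negative controls, and 10 bright ones were set aside. The test design, fixed before the data were examined, assumed raw signals with a detection p-value for each probe, which these tables do not hold. Signals were therefore raised from the log2 scale, background-corrected by normexp on the negative controls and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3 (robust, offset 16). The detection p-value of a probe on an array was computed as the share of negative controls at or above its signal, with 1 added to both numbers of the share. Probes with a detection p-value under 0.01 on at least 5 of the 15 arrays were kept, which left 12077 probes (47.0%). Gene symbols came from the platform annotation. They were matched by gene identifier to the RefSeq genes of the mouse assembly GRCm38.p6 for 23962 probes, and 0 symbols needed an update. Altogether 23978 probes had 1 symbol, 0 had several and 1719 had none. Each of the 8442 genes was represented by its kept probe of highest mean, and 2163 genes had more than 1 kept probe. The 707 kept probes without a symbol were tested and not named. The position of a probe in its transcript is not given in the sources used here, so no coordinates are given.

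Linear models were fitted with lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjustment over all kept probes and calls at an adjusted p under 0.05. KO outer and KO inner layers were compared over the 10 KO arrays with the animal as a block. The numbers pair the KO layers because the series states that both came from the same animals. Deviations of the 2 layers of 1 animal from their group means correlated with r of 0.568, 0.243, 0.367, 0.383 and 0.777 for animals 1 to 5, across genes, and each array correlated best with its own number. Inner and outer layers were each compared with WT over 10 arrays, and KO animals with WT over the means of both layers of an animal. A log2 difference is given with its standard error (SE) and a group mean with its SD. The number of arrays limits the precision of all of these.

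Fixed before the data were examined were 27 gene lists. The cell type lists were markers of the CA3 field, the CA1 and CA2 fields, dentate granule neurons, pyramidal glutamatergic neurons, Cajal-Retzius neurons, subplate and early-born neurons, GABAergic interneurons, intermediate progenitors and newborn neurons, radial glia, astrocytes, the oligodendrocyte lineage, microglia, endothelial and mural cells, meningeal fibroblasts, red blood cells, and choroid plexus and ependyma. The others were cell cycle, doublecortin family and microtubule, reelin pathway and neuronal migration, axon guidance and cell adhesion, synapse and excitability, immediate early, oxidative phosphorylation, Golgi and secretory pathway, endoplasmic reticulum stress and apoptosis, heat shock and hypoxia, and ribosomal protein genes. The 24 lists with at least 4 measured genes were tested with camera of limma at a preset correlation of 0.01, and again with the correlation estimated. Lists of skeletal muscle, bone and cartilage, skin and myeloid blood cell genes were written after the arrays had been seen to differ in such transcripts.

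Named genes followed a rule fixed in advance. For each comparison it took the 12 genes higher and the 12 genes lower with the largest log2 difference among those called, if at least 4 of the 5 animals moved that way or, against WT, at least 4 of 5 KO values lay beyond the WT mean. Genes known only by a clone or locus name were counted and not named. The rule added up to 4 members of each called list by smallest p, and always Dcx, Dclk1 and Dclk2. Where a probe was below detection on all 5 arrays of a group, the fold is a bound. It sets the mean of the brighter group against the mean over the dim arrays of the lowest detected signal, or of the probe's own signal where that was higher.

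Other settings chosen in advance were the authors' scaled and shifted scores, no background correction, median scaling, other filters on dim probes, the mean of a gene's probes, eBayes with trend, array weights, all arrays in 1 fit, other thresholds, the pairing, and each replicate left out. Added after seeing the data were fits with the array batch as a term, fits of the unshifted arrays alone, and fits that left out arrays with muscle or bone transcripts or took their level as a covariate. With the batch as a term, or within the unshifted arrays, a difference from WT is that of KO animal 5, which is assumed to vary like the other arrays. The fits without the arrays high in muscle or bone transcripts set shifted KO arrays against unshifted WT arrays for the inner layer and for KO animals, so the batch and the group cannot be told apart in them. The steps were tested on simulated arrays with the mean and spread of the real ones, over 12077 probes of which 200 were changed. Between the KO layers 22.8%, 86.2% and 93.7% of probes changed 1.5-fold, 2-fold and 3-fold were recovered, for the inner layer against WT 48.5%, 84.6% and 92.9%, for the outer layer 47.5%, 85.9% and 92.9%, and for KO animals 61.2%, 93.2% and 98.3%. Of the unchanged probes, 5, 8, 4 and 11 were called in these 4 comparisons. A batch shift of the 8 arrays was also simulated, drawn for each probe with an SD of 1 on the log2 scale. Its size was chosen and not taken from the data, so the counts under it hold for that size only. The spread used already held the real difference between shifted and unshifted KO arrays. Without a batch term, 6421, 6283 and 6949 unchanged probes were called in the 3 comparisons with WT. With the batch as a term this fell to 5, 1 and 2. Of changes of 1.5-fold, 2-fold and 3-fold, 4.5%, 42.3% and 67.9% were then recovered for the inner layer, 3.4%, 33.8% and 72.9% for the outer layer, and 6.0%, 52.1% and 76.7% for KO animals. A shifted list was called in each of the 4 comparisons with 0 other lists called. The simulated probes varied independently of each other, so calls of lists whose genes vary together were not tested. The 2 layers of a simulated animal were drawn independently too, while the real ones correlated with r of 0.243 to 0.777. The recovery given may therefore be too high for KO animals and too low between the KO layers. On the real arrays the estimated correlation within a list reached 0.875, for red blood cell genes between the KO layers. Figures were drawn with matplotlib 3.10.9.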

Results

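The CA3 field is the part of the hippocampal pyramidal cell layer that receives the mossy fibres of the dentate gyrus. Doublecortin, the product of Dcx, is a microtubule-associated protein of migrating neurons. In the newborn Dcx KO mouse the CA3 layer is split, and its inner and outer parts were dissected separately from 5 animals. The CA3 layer of 5 WT mice served as the control. The comparisons ask which transcripts differ between the 2 KO layers, and how each layer and the genotype as a whole differ from WT. Between 10718 and 12072 probes were detected per array, and the median log2 signal of an array lay between 6.49 and 6.98. Array pairs correlated with r between 0.936 and 0.993 across probes, and no pair was close enough to be 1 sample deposited more than once.

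Arrays differed in ways that the groups do not explain. The first principal component held 40.2% of the variance and parted the 8 shifted arrays, all from KO animals 1 to 4, from the 7 unshifted arrays, which were both layers of KO animal 5 and the 5 WT arrays. The Y-linked gene Eif2s3y, detected on all 15 arrays, was at 8.08 or more on the shifted and 7.17 or less on the unshifted arrays, and Kdm5d at 5.41 or more and 5.13 or less. Uty did not part the arrays, Xist was below detection on all 15, and the sex of the animals is not given in the sources used here. A comparison of KO layers within an animal lies inside 1 batch, and a comparison with WT has 1 KO animal in the batch of the WT arrays. Skeletal muscle and bone transcripts also stood high on 6 arrays. The mean log2 level of 9 muscle genes, among them Myl1, Acta1 and Myh8, was 7.76 to 11.3 on inner arrays 1, 2 and 5 and WT arrays 1, 2 and 3, and 4.87 to 5.69 on the other 9. Bone and cartilage genes such as Col1a1, Ctsk and Ibsp were high on the same arrays except WT 2 (5.19), and reached 6.83 on outer array 1. Keratinocyte genes were highest on WT 1 (7.32) and inner 5 (6.68), and myeloid genes on inner 2 (7.34) and inner 1 (7.04).

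**Figure D1:**
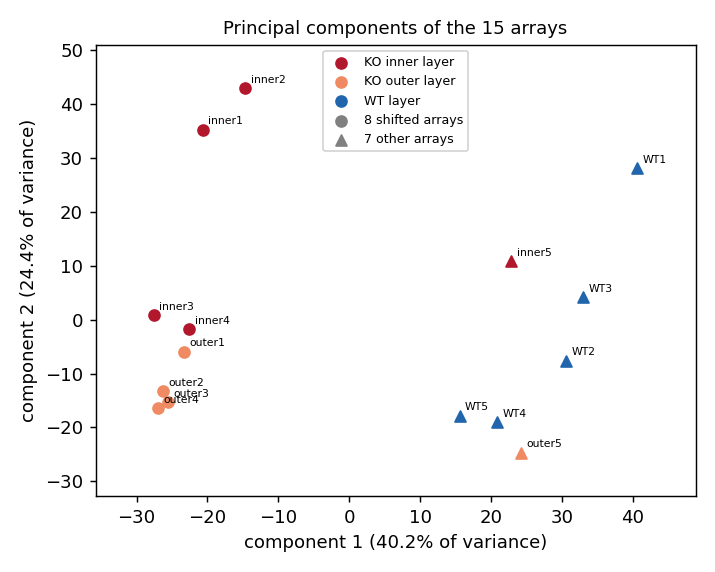
Position of each of the 15 arrays on the first (horizontal axis) and second (vertical axis) principal components of the normalized log2 values, without units, with circles for the 8 shifted and triangles for the 7 unshifted arrays. The first component, with 40.2% of the variance, separates circles from triangles, and both KO arrays of animal 5 lie on the side of the WT arrays.

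**Figure D2:**
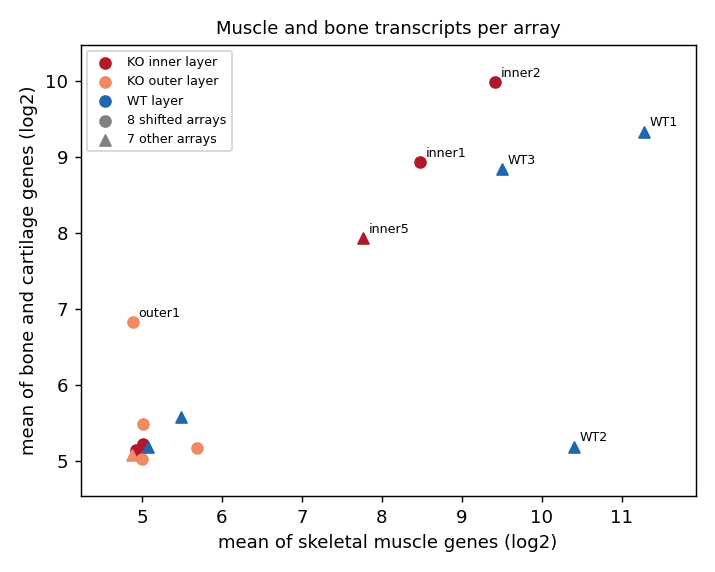
Mean log2 level of skeletal muscle genes (horizontal axis) and of bone and cartilage genes (vertical axis) on each of the 15 arrays, coloured by group. Inner arrays 1, 2 and 5 and WT arrays 1, 2 and 3 lie at muscle levels of 7.76 or more, and the other 9 arrays at 5.69 or less.

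Dcx transcript was lower on every KO array than on every WT array. Its brighter detected probe had a mean log2 signal of 10.49 ± 0.12 (SD, n = 5) in the inner layer, 10.61 ± 0.08 (SD, n = 5) in the outer layer and 11.96 ± 0.12 (SD, n = 5) in WT, and the highest KO value (10.74) lay below the lowest WT value (11.76). KO animals differed from WT by −1.41 ± 0.08 (SE, limma adjusted p = 3.49e-05), which is 2.66-fold lower in 5 of 5 animals. The other detected probe differed by −1.05, and a further Dcx probe was below detection on all 15 arrays. The signal that was left was well above background, and the place of these probes relative to the deleted part of the gene is not given in the sources used here. With the batch as a term the difference was −1.51 ± 0.14 (adjusted p = 0.00795). Dcx did not differ detectably between the KO layers (0.12 ± 0.07, adjusted p = 0.264). Its relatives Dclk1 and Dclk2 passed the test in no comparison, with differences between KO animals and WT of −0.22 and 0.10 (adjusted p of 0.0874 and 0.490).

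**Figure D3:**
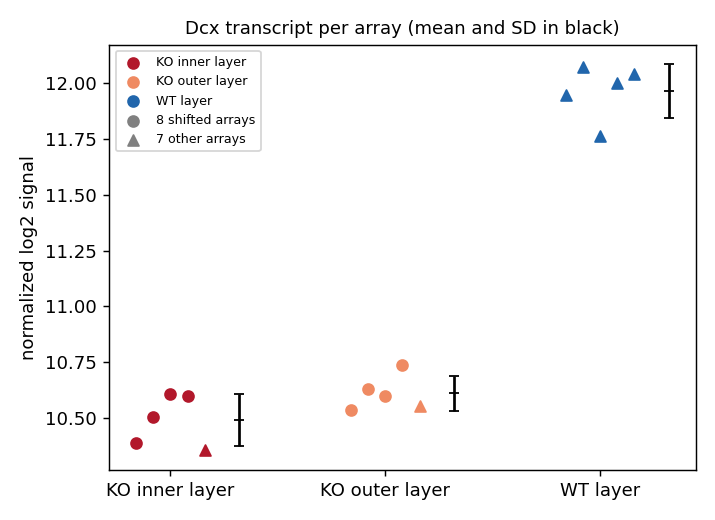
Normalized log2 signal of the brighter Dcx probe (vertical axis) on each array of the 3 groups, with the mean and SD in black. All 10 KO arrays lie at 10.74 or below and all 5 WT arrays at 11.76 or above.

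Between the KO layers, Rasgrp1 and Cckbr were lower and Tacr3 and Chodl higher in the outer layer. Rasgrp1, an activator of Ras, was 5.92-fold lower in the outer layer (log2 difference −2.56 ± 0.07 SE, adjusted p = 8.58e-06, 5 of 5 animals), and Cckbr, a cholecystokinin receptor, 5.01-fold lower (−2.32 ± 0.09). The cell adhesion gene Cdh13 (−2.04 ± 0.10), the ion transport regulator Fxyd7 (−1.997 ± 0.10) and the retinoic acid binding protein gene Crabp1 (−1.88 ± 0.11) were lower in all 5 animals too. Tacr3, the neurokinin 3 receptor, was 3.35-fold higher (1.74 ± 0.13), followed by Chodl (1.66 ± 0.15), the claudin gene Cldn3 (1.62 ± 0.08), Igfbpl1 (1.48 ± 0.10), Ptx3 (1.41 ± 0.15) and the neurogenic transcription factor gene Insm1 (1.41 ± 0.10). Mb21d2, Rnd2, Ssbp2, Emilin2, the calretinin gene Calb2 and Tmem132c were 2.31-fold to 2.58-fold higher, each in 5 of 5 animals. In all, 805 genes were higher and 960 lower in the outer layer (1765 of 8442, 20.9%, and 983 in all without animal 1), of which 22 were higher and 121 lower by at least 2-fold. The authors' scaled values gave 59.5% of the calls as higher and quantile normalization 45.6%. Their shift differed between inner and outer arrays, so it changes the outer minus inner difference itself.

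The outer layer also had less Acta1, which encodes skeletal muscle actin (−2.16 ± 0.57, 4 of 5 animals), Serpinf1 (−2.17 ± 0.57), the collagen gene Col6a1 (−1.95 ± 0.56), the matrix gene Bgn (−1.92 ± 0.53), Mmp9 (−2.02 ± 0.49), the neutrophil gene S100a8 (−1.95 ± 0.51, 4 of 5 animals) and Fxyd5 (−2.005 ± 0.40). Muscle and bone transcripts were high on inner arrays 1, 2 and 5. In animals 3 and 4, whose arrays were low in them, the difference was −0.35 for Acta1, −0.42 for Serpinf1, −0.33 for Col6a1, −0.46 for Bgn, −0.75 for Mmp9, −0.75 for S100a8 and −1.60 for Fxyd5, against −2.60 for Rasgrp1, −2.36 for Cckbr and −1.91 for Cdh13. These 2 animals alone gave 94 genes higher and 213 lower, of which 289 were called with the same direction in the fit of 5 animals.

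**Figure D4:**
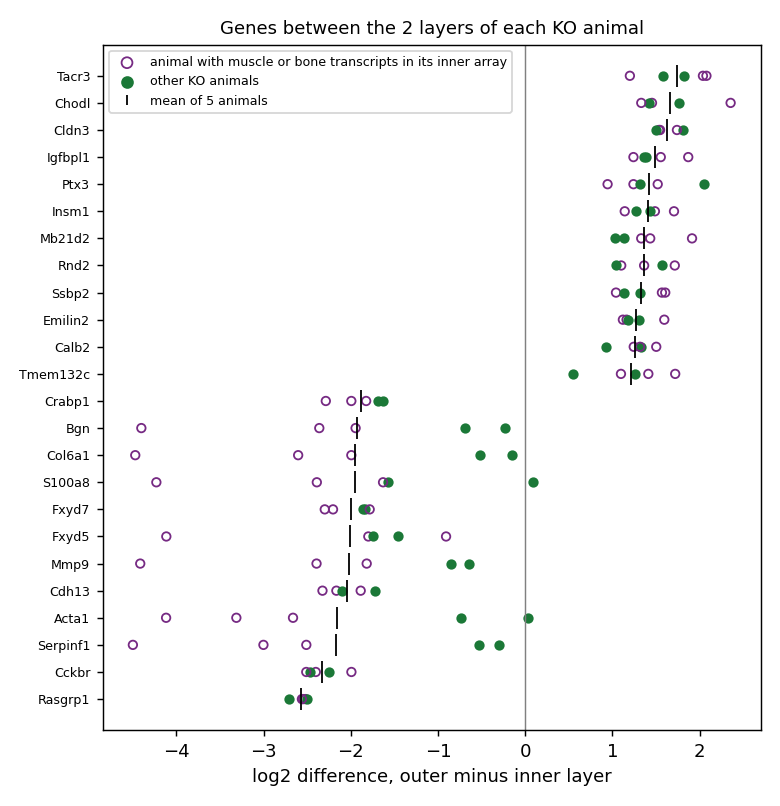
Outer minus inner difference on the log2 scale (horizontal axis) in each of the 5 KO animals, for the 12 named genes higher and the 12 lower in the outer layer, with the mean as a black bar. Open circles are animals 1, 2 and 5, whose inner arrays carried muscle or bone transcripts, and filled circles are animals 3 and 4, in which Rasgrp1 stays at −2.60 and Acta1 at −0.35.

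Of the lists, intermediate progenitor and newborn neuron markers rose in the outer layer and 13 other lists fell. Of 7 newborn neuron genes 6 rose, led by Igfbpl1, Insm1 and the small GTPase gene Rnd2 (1.36 ± 0.11), and Gadd45g fell by 0.87 on the log2 scale; the same 6 and 1 passed when adjusted over the list alone (camera adjusted p = 0.00124). With an estimated correlation camera called 0 of the 24 lists in each of the 4 comparisons, and the lowest adjusted p here was 0.165 (4 lists at an unadjusted p under 0.05). Radial glia markers fell in 8 of 11 genes (adjusted p = 7.28e-05; 8 adjusted over the list alone), among them Slc1a3, a glutamate transporter (−0.72), and the extracellular matrix gene Tnc (−1.22). Ttyh1 (−0.73) and Dbi (−0.68) fell as well, although another Dbi probe moved the other way. The oligodendrocyte lineage fell in 6 of 10 genes (adjusted p = 0.000408; 6 over the list alone), with Pdgfra at −1.21, Olig1 at −1.11, Bcas1 at −0.51 and Mbp at −0.42. Astrocyte markers fell in 4 of 9 (adjusted p = 0.00242; 5 over the list alone), with Mt1 at −1.54, Aldoc and Aldh1l1 at −1.11 and Clu at −0.67. Endothelial and mural cell markers fell in 9 of 14 (adjusted p = 7.28e-05; 10 over the list alone), with Egfl7 at −0.90, Esam at −0.82, Pecam1 at −0.78 and Itm2a at −0.65. Cell cycle genes fell in 7 of 15 and rose in 1, the same when adjusted over the list alone (adjusted p = 0.00124), with Top2a at −0.96, Cdk1 at −0.86, Cenpa at −0.76 and Cdc20 at −0.55. With an estimated correlation these 5 lists had an adjusted p of 0.165 (radial glia), 0.165 (oligodendrocyte), 0.354 (astrocyte), 0.248 (endothelial) and 0.248 (cell cycle).

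Pyramidal neuron markers fell in 6 of 13 genes and rose in 2, Slc17a6 (0.35) and Neurod6 (0.47) (adjusted p = 0.0108; 8 and 2 adjusted over the list alone; estimated-correlation adjusted p = 0.248), with the kinase gene Camk2a at −1.41, the vesicular glutamate transporter gene Slc17a7 at −1.22, Cux2 at −0.61 and Nrgn at −0.53. GABAergic markers fell in 6 of 12 and rose in 2, the same adjusted over the list alone (adjusted p = 0.0276; estimated-correlation adjusted p = 0.387). Slc32a1 (−0.55) and Npas1 (−0.64) fell, and Calb2 (1.26) and Nr2f2 (1.14) rose. Synapse and excitability genes fell in 7 of 21 (adjusted p = 0.00242; 9 over the list alone; estimated-correlation adjusted p = 0.165), with Kcna1 at −0.99, Nrxn3 at −0.84, Syt1 at −0.40 and Gria1 at −0.39. Immediate early genes fell in 4 of 6, with Egr1 at −1.31, Arc at −0.85 and Jun at −0.46, and Dusp1 rose (0.34), the same 4 and 1 adjusted over the list alone (adjusted p = 0.0352; estimated-correlation adjusted p = 0.387). Oxidative phosphorylation genes fell in 3 of 22, namely Cox8a (−0.37), Uqcrc1 (−0.28) and Cox6a1 (−0.26), with 2 over the list alone (adjusted p = 0.0332; estimated-correlation adjusted p = 0.387), and Cyc1 at −0.25 did not pass (adjusted p = 0.0590).

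Microglia, meningeal fibroblast and red blood cell lists fell in the outer layer too. Microglia markers fell in 3 of 7 genes (adjusted p = 0.00659; 4 over the list alone; estimated-correlation adjusted p = 0.387), with Laptm5 at −1.57, C1qb at −0.95 and Cx3cr1 at −0.82, and C1qc at −0.79 did not pass (adjusted p = 0.0720). Meningeal fibroblast markers fell in 2 of 9, Bgn and Igf2 (−1.48), with 6 over the list alone (adjusted p = 0.0148; estimated-correlation adjusted p = 0.403), and Col1a1 (−2.75 ± 0.99) and Col1a2 (−0.44) did not pass. Red blood cell genes fell in 2 of 4, Alas2 (−0.79) and Hba-a1 (−0.47), with 3 over the list alone (adjusted p = 0.0309; estimated-correlation adjusted p = 0.387), and Slc4a1 (−1.10) and Hbb-b2 (−0.55) did not pass. In animals 3 and 4, whose inner arrays were low in muscle and bone transcripts, these 3 lists were not called (adjusted p of 0.111, 0.529 and 0.111). Their medians there were −0.19 for microglia, 0.09 for meningeal and −0.27 for red blood cell genes, against −0.79, −1.48 and −0.67 in all 5 animals, and Cx3cr1 was at −0.56, C1qb at −0.56 and Laptm5 at −0.51. Also not called in these 2 animals were the synapse (0.0898), immediate early (0.358) and oxidative phosphorylation (0.362) lists. Their medians were −0.19, −0.32 and −0.09, against −0.17, −0.55 and −0.08 in all 5, so the synapse and oxidative phosphorylation medians were as large with fewer animals. The other 8 lists were called.

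Lists that passed neither test between the KO layers were those of the CA3 field (2 of 6 genes lower, adjusted p = 0.457, and 1 higher and 2 lower adjusted over the list alone, with a median difference of 0.01, a mean of −0.18 and a test direction of down), the CA1 and CA2 fields (2 higher and 4 lower of 8, 0.266), subplate and early-born neurons (1 higher and 1 lower of 7, and 1 and 2 over the list alone, 0.630), and doublecortin family and microtubule genes (1 higher and 3 lower of 25, 0.318). Reelin pathway and migration genes (2 higher and 1 lower of 17), axon guidance and adhesion genes (8 higher and 5 lower of 22, and 10 and 6 adjusted over the list alone), Golgi and secretory genes (2 higher of 23, and 0 over the list alone) and stress and apoptosis genes (2 lower of 12) each had an adjusted p of 0.227. Heat shock and hypoxia genes (2 lower of 9, 0.377) and ribosomal protein genes (0 of 17 called by limma, adjusted p = 0.629) did not pass either. For the lists without a second count here, the count adjusted over the list alone was the same. Too few genes were measured to test the lists of dentate granule neurons (3), Cajal-Retzius neurons (3) and choroid plexus and ependyma (2).

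In the inner KO layer, Olig1 and Aldoc were above WT, and Cldn3 and Dcx were below it. Olig1, a transcription factor gene of the oligodendrocyte lineage, was 4.99-fold higher (2.32 ± 0.17 SE, adjusted p = 9.13e-05, 5 of 5 arrays), and 1.72 with the batch as a term. The astrocyte glycolytic gene Aldoc (1.80 ± 0.17), Igfbp7 (1.85 ± 0.24), the histone gene H2bc4 (2.17 ± 0.23) and Il16 (1.81 ± 0.29) were higher, with 1.63, 1.19, 1.63 and 0.75 under the batch term. St18 (2.31 ± 0.40), Prmt8 (2.20 ± 0.46), Pabpc1 (1.89 ± 0.35), Ankrd46 (1.87 ± 0.39), Dynlt3 (1.87 ± 0.40), Pgrmc1 (1.86 ± 0.40, 4 of 5 arrays) and Atp6v1a (1.84 ± 0.34) were also higher. Their batch-term differences were between −0.01 and 0.75, and other Pabpc1 probes moved the other way. Lower than WT were Cldn3 (−1.68 ± 0.12), Dcx (−1.47 ± 0.09), Igfbpl1 (−1.45 ± 0.16), Wfdc2 (−1.44 ± 0.41), Kcp (−1.41 ± 0.22), Cryab (−1.28 ± 0.39), Emilin2 (−1.27 ± 0.09) and the gap junction gene Gja1 (−1.20 ± 0.36). Tmem132c, Tiam2, Calb2 and Plekhg2 were 2.28-fold to 2.31-fold lower. All 12 kept their sign under the batch term, as did 97.3% of all 1323 genes called lower. That difference rests on inner array 5, which was among the arrays these genes were selected on, so the sign is no separate test.

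Limma called 1155 genes higher and 1323 lower in the inner layer (2478 of 8442), with 1633 in all without WT 3. Without the arrays high in muscle or bone transcripts 1346 were called. That fit set inner 3 and 4, both shifted, against WT 4 and 5, both unshifted, so that layer and batch coincide in it. With the batch as a term 3 genes higher and 4 lower were left (835 at an unadjusted p under 0.05), and within the unshifted arrays, 1 inner array against 5 WT, 0 (921 unadjusted). The 7 genes were Dcx (−1.61), Cldn3 (−1.52), Insm1 (−1.37), Emilin2 (−1.33), Olig1 (1.72), Slc22a21 (1.13) and Akap7 (0.99), the last 2 named after their values were seen. A fit of all 15 arrays with the batch as a term and the animal as a random block called 105 genes, 82 higher and 23 lower. Over the 1155 higher genes the median difference was 0.69 in all animals and 0.25 within the unshifted arrays, and over the 1323 lower genes −0.46 and −0.27. Median scaling gave 79.9% of the calls as higher and quantile normalization 46.6%.

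Of the lists, 8 were higher in the inner layer than in WT, and their lowest adjusted p with an estimated correlation was 0.163 (3 lists at an unadjusted p under 0.05). With inner array 5 left out, 3 lists were called at the preset correlation. Radial glia markers rose in 7 of 11 genes and fell in 1 (adjusted p = 0.000212; 9 and 1 adjusted over the list alone), with Nes at 1.03, Slc1a3 at 0.96, Ttyh1 at 0.89 and Hes1 at 0.75. GABAergic markers rose in 8 of 12 and fell in 2, the same over the list alone (adjusted p = 0.0164), with the glutamate decarboxylase gene Gad1 at 1.17, Sst at 0.99 and Dlx1 at 0.80, and Calb2 at −1.19. Cell cycle genes rose in 5 of 15 and fell in 2, the same over the list alone (adjusted p = 0.0178), with Cdk1 at 1.08, Top2a at 1.01 and Cenpa at 0.97, and Tyms at −0.68. Astrocyte markers rose in 4 of 9 and fell in 1, the same over the list alone (adjusted p = 0.0178). Besides Aldoc these were Mt1 (1.30), Aldh1l1 (1.13) and Sparcl1, which was not detected on any WT array and was at least 1.69-fold higher over the 5 inner arrays (log2 difference 0.48 under the batch term). Pyramidal markers rose in 7 of 13 and fell in 1 (adjusted p = 0.0318; 7 and 2 over the list alone), with Camk2a at 0.87, Slc17a7 at 0.66, Cux2 at 0.61 and Nrgn at 0.50.

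Synapse and excitability genes rose in 7 of 21 (adjusted p = 0.0178; 7 over the list alone), with Nrxn3 at 1.06, Kcna1 at 0.80 and Syt1 at 0.51. Nlgn1, not detected on any WT array, was at least 1.82-fold higher over the 5 inner arrays (log2 difference 0.20 under the batch term). Endothelial and mural cell markers rose in 4 of 14 (adjusted p = 0.0198; 4 over the list alone), with Rgs5 at 0.84, Flt1 at 0.64, Esam at 0.55 and Pdgfrb at 0.55. Oxidative phosphorylation genes rose in 8 of 22 (adjusted p = 0.0201; 8 over the list alone), with Atp5a1 at 1.73, Ndufb9 at 1.63, Cox6c at 1.21 and Sdhb at 0.52. With an estimated correlation the adjusted p was 0.163 for radial glia, 0.328 for GABAergic, 0.397 for cell cycle, 0.354 for astrocyte, 0.215 for pyramidal, 0.163 for synapse, 0.446 for endothelial and 0.328 for oxidative phosphorylation genes. Inner array 5, on which the differences under the batch term rest, was high in muscle (7.76), bone (7.94) and skin (6.68) transcripts. With the batch as a term, where the difference rests on inner array 5 alone against WT, 8 lists were called higher and 1 lower at the preset correlation, and 0 with an estimated one (lowest adjusted p of 0.0753, and 5 lists at an unadjusted p under 0.05). Oxidative phosphorylation genes were no longer called (adjusted p = 0.349; Atp5a1 0.25, Ndufb9 0.01, Cox6c 0.23, Sdhb 0.13), and oligodendrocyte lineage markers were called higher (adjusted p = 0.00135, against 0.0655 without the term; estimated-correlation adjusted p = 0.131). The list called lower held intermediate progenitor and newborn neuron markers, with a median of −0.65 (adjusted p = 0.00380; estimated-correlation adjusted p = 0.206). Without the term its median was −0.80 and it did not pass (adjusted p = 0.0791; 4 of 7 genes lower and 1 higher, the same over the list alone). Without the arrays high in muscle or bone transcripts, in the fit in which layer and batch coincide, 3 of the 8 calls ended, those of astrocyte (adjusted p = 0.189, median 0.23 against 0.61), pyramidal (0.0668, 0.29 against 0.41) and synapse genes (0.0667, 0.07 against 0.14).

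In the outer KO layer, the called genes below WT included Acta1, Cckbr and Dcx. Acta1 (−2.99 ± 0.89), the muscle enolase gene Eno3 (−2.34 ± 0.63), Myl4 (−1.43 ± 0.44), Tnnt1 (−1.31 ± 0.33) and Cox7a1 (−1.30 ± 0.37) were lower than in WT, whose arrays 1, 2 and 3 were high in muscle transcripts. Without the arrays high in them these 5 genes lay between −0.75 and −0.49. Cckbr (−1.69 ± 0.18 SE, adjusted p = 0.00436, 5 of 5 arrays), Dcx (−1.35 ± 0.09), the receptor gene Gpr83 (−1.33 ± 0.19), Rasgrp1 (−1.08 ± 0.24), the heparan sulfate enzyme gene Hs3st1 (−1.05 ± 0.14), Tnfrsf12a (−1.03 ± 0.17) and Pglyrp1 (−0.997 ± 0.28) were lower too. These 12 genes kept their sign under the batch term, as did 98.8% of all 575 genes called lower. Outer array 5, on which that sign rests, was among the arrays they were selected on, so it is no separate test. Rgma, which encodes a guidance molecule, was 4.18-fold higher (2.06 ± 0.48), and Vps26b (2.04 ± 0.47), Prmt8 (1.98 ± 0.42), Zc3h15 (1.89 ± 0.46), Vapa (1.89 ± 0.42), Bcas2 (1.88 ± 0.48), Ptma (1.87 ± 0.44), Abhd17c (1.87 ± 0.48), Stmn1 (1.86 ± 0.41), Ankrd46 (1.83 ± 0.36), Lrrn2 (1.78 ± 0.52) and Kpnb1 (1.74 ± 0.45) were also higher. Prmt8, Vapa, Stmn1 and Ankrd46 were so on 5 of 5 outer arrays and the other 8 on 4 of 5. Under the batch term these 12 lay between −0.59 and 0.21, and 4 of them kept their sign.

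Limma called 703 genes higher and 575 lower in the outer layer (1278 of 8442), and with the batch as a term 1 gene, Dcx (545 at an unadjusted p under 0.05). Leaving out 1 array gave 3 genes (outer 3), 3 (outer 4), 20 (outer 2), 757 (outer 1) or 2645 (outer 5), and 406, 173, 190 and 318 for WT 1, 2, 3 and 4. Without the arrays high in muscle or bone transcripts 1 gene was called, and 1 with their level as a covariate. Within the unshifted arrays 0 were called (603 unadjusted), and over the 703 higher genes the median difference was 0.82 in all animals and 0.08 there, against −0.45 and −0.25 over the 575 lower genes. Median scaling gave 92.7% and the authors' scaled values 71.6% of calls as higher, against 55.0% with quantile normalization. Median scaling moved the median difference of all genes from −0.08 to 0.04 here and from 0.03 to 0.14 between the KO layers. Camera called 0 of the 24 lists (lowest adjusted p of 0.142, and 4 lists at an unadjusted p under 0.05), and with an estimated correlation the lowest adjusted p was 0.683. In these lists, reelin pathway and migration genes rose in 4 of 17 (7 higher and 2 lower adjusted over the list alone, adjusted p = 0.142). Oxidative phosphorylation genes rose in 6 of 22 (6 over the list alone, 0.424), with a median of −0.01 where the test's direction was up, and pyramidal markers rose in 1 and fell in 3 of 13 (1 and 3 over the list alone, 0.628).

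Averaged over both layers, KO animals had less Dcx than WT and more Olig1. Olig1 was 3.40-fold higher (1.77 ± 0.17 SE, adjusted p = 0.00280, 5 of 5 animals), with 1.16 under the batch term. Prmt8 (2.09 ± 0.44), Rgma (1.93 ± 0.46), Vps26b (1.91 ± 0.42), Ankrd46 (1.85 ± 0.37), Zc3h15 (1.82 ± 0.45), Pabpc1 (1.81 ± 0.39), Vapa (1.80 ± 0.45), St18 (1.79 ± 0.36), Pgrmc1 (1.77 ± 0.40), Bcas2 (1.74 ± 0.43) and Atp6v1a (1.73 ± 0.36) were higher as well, with batch-term differences between −0.24 and 0.42. Rgma, Vps26b, Zc3h15, Vapa, Pgrmc1 and Bcas2 were higher in 4 of 5 animals and the others in 5. Other Pabpc1 probes moved the other way. After Dcx, the genes lowest against WT were Cldn3 (−0.87 ± 0.11), Pi16 (−0.82 ± 0.18), Kcp (−0.82 ± 0.19), Pomt2 (−0.81 ± 0.16), Itprip (−0.81 ± 0.17), Ccdc134 (−0.80 ± 0.12) and Fbxo30 (−0.80 ± 0.17). The lipid transporter gene Abca7, Gja1 (4 of 5 animals), Hrob and Tiam2 were 1.69-fold to 1.70-fold lower. These 12 genes kept their sign under the batch term, as did 98.8% of all 921 genes called lower. KO animal 5, on which that sign rests, was among the animals they were selected on, so it is no separate test.

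Limma called 954 genes higher and 921 lower in KO animals (1875 of 8442), and with the batch as a term 1, Dcx (316 at an unadjusted p under 0.05). Leaving out 1 animal gave 13 genes (KO 3), 15 (KO 4), 21 (KO 2), 1058 (KO 1) or 3047 (KO 5), and 952, 785 and 902 for WT 2, 3 and 4, and the muscle and bone level as a covariate gave 1092. Within the unshifted arrays, 1 KO animal against 5 WT, 0 were called (283 unadjusted). The median difference of the 954 higher genes was 0.69 in all animals and 0.09 within the unshifted arrays, where 641 kept their direction, and that of the 921 lower genes −0.40 and −0.20, where 910 did. Median scaling gave 91.4% and the authors' scaled values 67.7% of calls as higher, against 50.9% with quantile normalization. Radial glia markers rose in 6 of 11 genes (adjusted p = 0.00258; 6 higher and 1 lower adjusted over the list alone; estimated-correlation adjusted p = 0.197), with Sox9 at 0.78, Nes at 0.76, Slc1a3 at 0.60 and Ttyh1 at 0.53, of which another probe moved the other way. GABAergic markers rose in 6 of 12 and fell in 1 (adjusted p = 0.0254; 7 and 1 over the list alone; estimated-correlation adjusted p = 0.516), with Gad1 at 0.93, Sst at 0.84, Dlx2 at 0.82 and Dlx1 at 0.60. Under the batch term these 4 genes were at 0.53, 0.33, 0.04 and 0.84. The CA3 field list was called higher with 2 of 6 genes called, St18 and Cpne4 (0.28), 2 also over the list alone (adjusted p = 0.0254; estimated-correlation adjusted p = 0.516), while Bok (0.34, with another probe moving the other way) and Socs2 (0.19) did not pass. In the fit with the batch as a term, where KO animal 5 alone stands against WT, 7 lists were called at the preset correlation and 0 with an estimated one (lowest adjusted p of 0.0611, and 3 lists at an unadjusted p under 0.05). The CA3 field list was not called (adjusted p = 0.339; St18 0.42, Bok −0.12). The inner array of KO animal 5 was high in muscle (7.76), bone (7.94) and skin (6.68) transcripts. Leaving out the arrays high in muscle or bone transcripts left KO animals 3 and 4, both shifted, and WT 4 and 5, both unshifted, so that genotype and batch coincide. In that fit the GABAergic (adjusted p = 0.0607, median 0.29 against 0.36) and CA3 field (0.0907, 0.23 against 0.24) calls ended.

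Both layers were compared with the same WT arrays, and 724 genes were called in the same direction in both, 483 higher and 241 lower. Independent lists of the same sizes would share 186. Unchanged groups simulated against the same WT arrays shared 0 on average over 100 draws. Calls at an adjusted p under 0.05 are rare where no gene is changed, so this 0 was nearly fixed in advance and does not gauge the 724. Differences from WT in the 2 layers correlated with r = 0.653 across genes, which are not independent replicates, against 0.679 for the simulated unchanged groups. Their covariance was 0.122 against 0.0276 simulated, a difference of 0.0946. With the WT arrays split between the layers in the 10 possible ways, a median of 1 gene (1 to 4) was called in both, and the median correlation was 0.532. The layers also share their animals and array batches, so the shared calls and the covariance do not tell the genotype from the batch. With the batch as a term 1 gene was called in both.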

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

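The tests of the array batch, of foreign tissue between the KO layers, of dilution, and of the batch, group and layer of the muscle transcripts were chosen after the result was seen, and the test of further muscle genes was chosen before it.

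Genes that moved in opposite directions against WT in the 2 KO layers numbered 34, and all 34 were also called between the layers. That call uses the same KO arrays and follows from their selection, so it is no separate test. In 33 of them the inner layer was above WT and the outer layer below it. The genes with the smallest p between the layers, chosen after their values were seen, were Rasgrp1 (1.49 inner and −1.08 outer against WT), Hcrtr1 (1.10 and −0.75), Cdh13 (1.18 and −0.86), Fxyd7 (1.13 and −0.87) and Vsnl1 (0.82 and −0.65). Camk2a (0.87 and −0.54), Slc17a7 (0.66 and −0.56) and the doublecortin relative Dclk3 (0.39 and −0.45) were among them, and Slc25a30 was the exception (−0.42 and 0.39). All 34 kept both signs within the unshifted arrays, where each layer has 1 array, which was also among those they were selected on. Outside the measured probes, 9 of the 10 bright control entries were higher on all 8 shifted arrays than on all 7 unshifted ones.

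In 432 sets of 5 arrays, 67 held an array whose gap to its nearest neighbour, divided by the range of the set, passed Dixon's critical value, where chance gives 21.6. That figure takes the sets as independent, which genes are not. Most of the 139 genes had been chosen on the same arrays for large differences or small p, so the excess over chance is no test. KO animal 5 was the lowest in both layers for 18 genes. The gap over the range was, for inner and outer, 0.872 and 0.888 for Abhd17c, 0.868 and 0.892 for Ankrd46, 0.773 and 0.840 for Atp5a1, 0.895 and 0.801 for Atp6v1a, 0.782 and 0.910 for Bcas2, and 0.872 and 0.835 for Cox6c. It was 0.720 and 0.834 for Dynlt3, 0.869 and 0.877 for Lrrn2, 0.900 and 0.933 for Pabpc1, 0.925 and 0.836 for Pgrmc1, 0.880 and 0.849 for Prmt8, and 0.798 and 0.777 for Ptma. For Rgma it was 0.825 and 0.959, for St18 0.740 and 0.848, for Stmn1 0.869 and 0.793, for Vapa 0.878 and 0.899, for Vps26b 0.861 and 0.855, and for Zc3h15 0.874 and 0.865. Inner array 5 alone was lowest for Dlx2 (0.745) and Ndufb9 (0.794) and highest for the skin genes (0.760). Outer array 5 alone was lowest for Igfbp7 (0.7104), Il16 (0.769), Kpnb1 (0.816), Olig1 (0.754), Ptx3 (0.720) and Sparcl1 (0.781), and highest for Aldh1l1 (0.777).

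WT array 1, the highest in muscle transcripts, was highest for C1qb (0.712), Esam (0.845), Mt1 (0.841), Pecam1 (0.816) and Wfdc2 (0.875) and lowest for Tmem132c (0.728). Other WT arrays stood apart for Nlgn1 (WT 2 lowest, 0.732), Stmn1 (WT 3 lowest, 0.736) and Sox9 (WT 5 highest, 0.729). Inner arrays did so for Alas2 (array 2 highest, 0.711), Tyms (array 2 lowest, 0.836), Sox9 (array 3 highest, 0.722) and Ssbp2 (array 1 lowest, 0.780). Among outer arrays, array 1 was highest for Bgn (0.789) and Pglyrp1 (0.761) and lowest for Gpr83 (0.738). Outer array 2 was highest for Aldoc (0.760) and lowest for Insm1 (0.761) and Tiam2 (0.881), array 3 highest for Fxyd7 (0.748), and array 4 highest for the skin genes (0.717).

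The genes called between KO animals and WT may in part reflect the array batch. The 954 genes called higher had a median difference of 0.69 in all animals and 0.09 (SD 0.253 across genes) within the unshifted arrays, a ratio of 0.133, as a batch would need, and the 921 called lower had −0.40 and −0.20, a ratio of 0.499, which leaves the batch open for them. Dcx differed by −1.51 within the unshifted arrays, which argues against the batch as its whole cause. KO animals 1 to 4 differed from KO animal 5, a single animal assumed to vary like the others, in 604 genes higher and 28 lower. Genotype and the sex of the animals stay open beside the batch. Y-linked Eif2s3y and Kdm5d part the arrays along the batch, but Eif2s3y was detected on all 15 arrays and Xist on 0, so a split of the arrays by sex was not shown. With 1 KO animal in the batch of the WT arrays, the fit with the batch as a term called 1 gene, Dcx.

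For the genes called between the KO layers, muscle and bone tissue in the inner arrays is a candidate cause. The median share of the difference left in animals 3 and 4 was 0.892 over all 1765 genes and 0.847 over the 121 genes at least 2-fold lower. These genes were called in a fit that includes animals 3 and 4, which favours genes that differ in them. The share is therefore no separate test of such tissue as the cause of either set. Such tissue stays open as a cause, and 34 of these 121 genes kept under 0.5 of their difference, among them Acta1 and Col6a1. Pyramidal neurons diluted by other cells in the inner layer would raise pyramidal markers in the outer layer, and in animals 3 and 4 their median was −0.31. A difference between the layers in the level of these genes per neuron would also move that median, so it does not exclude dilution. A biological difference between the layers stays open and was not tested apart from these explanations.

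Muscle, bone and skin transcripts on some arrays may come from tissue carried along in dissection. A further list of 20 muscle genes had 10 detected, none of them used to find the arrays. Their median lay at least 0.533 above the low arrays on each of the 6 high ones, up to 2.45 on WT 1. Probes were kept if detected on at least 5 arrays, so the 6 high arrays could bring in genes raised on them. These genes may also vary together with the muscle genes used to find the arrays. Their rise is therefore no separate test of tissue carried along in dissection, which stays open. The most abundant muscle and bone transcripts were Myl1 (13.1), Myh8 (13.0) and Acta1 (12.3) on WT 1 and Col1a1 (12.5) on inner array 2, and Col1a1 is also in the list of meningeal fibroblast markers. The tables argue against the batch as the whole cause, since the batch with fewer high arrays still held 2. They also argue against genotype or layer as the whole cause, since 2 groups held arrays of both kinds. The batch may still play a part. A part played by the layer stays open, since 3 inner and 0 outer arrays were high and in 3 of 3 KO animals with 1 high array it was the inner one (exact sign test, two-sided p = 0.25, the smallest these animals allow), and where such tissue, which microdissection should leave out, entered was not tested.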

How the results depend on the processing

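The fits with the array batch, of the unshifted arrays alone, and with the muscle and bone level or without the arrays high in it were chosen after seeing the data, and the other settings before. Dcx against WT kept its direction and call under 13 of 13 planned settings. On the log2 scale it was −1.48 to −1.23 under them, and under the authors' scores −1.06 in units of the array SD. With a replicate left out Dcx was at −1.46 to −1.39. Within the unshifted arrays it was −1.51 (adjusted p = 0.343), with 1 KO animal in the fit. Of the planned settings other than left-out replicates, 10 of 13 kept the gene count between the KO layers within 1.5 times, 10 of 13 that of the inner layer, 6 of 13 that of the outer layer and 7 of 13 that of KO animals. The cause of a change was not tested except where fewer arrays or a stricter threshold make it. Signal over background limits dim probes, as 47.0% of probes were kept.

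With at least 1.5-fold required, 617 genes were called between the layers, 1059 in the inner layer, 629 in the outer layer and 687 in KO animals. Median scaling gave 711, 957, 495 and 805, and 1 list in the outer layer, and reversed Dclk1 (0.15) between the layers and Dclk2 (−0.0719) in the inner layer. The authors' scaled values gave 1023 genes in the inner layer, 387 in the outer layer and 449 in KO animals, 72 shared by both layers and 5 lists in the outer layer. They reversed Dclk2 between the layers (−0.11) and in the outer layer (−0.0484), both in units of the array SD. At an adjusted p under 0.10 there were 2404 genes in the outer layer, 2907 in KO animals and 1473 shared. Array weights gave 3144 in the outer layer and 3434 in KO animals, and no filter 648 in the outer layer. With an estimated correlation camera called 0 lists between the layers, in the inner layer and in KO animals (4, 3 and 1 at an unadjusted p under 0.05).

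Without the replicate block 706 genes were called between the layers. The WT numbers do not pair with KO animals, as deviations of same-numbered arrays correlated with r of 0.343, −0.153, −0.307, 0.479 and −0.209 for inner and 0.165, −0.0925, −0.136, 0.0736 and −0.208 for outer arrays, across genes. The replicate block gave 4 genes in the outer layer and 1 in KO animals, and changed no other count by over 1.5 times. Since the numbers do not pair, these low counts do not show a weaker effect.

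With a replicate left out, 983 (without animal 1) to 1282 genes and 10 to 14 lists were called between the layers. In the inner layer it was 1633 (without WT 3) to 3257 genes, and 3 (without inner 5) to 11 lists. In the outer layer it was 3 to 2645 genes, with 3 without array 3 and 3 without array 4, 20 without array 2, 757 without array 1, 2645 without array 5, and 406, 173, 190 and 318 without WT 1, 2, 3 and 4, and 0 lists throughout. In KO animals it was 13 to 3047 genes, with 1058, 21, 13, 15 and 3047 without animals 1 to 5 and 952, 785 and 902 without WT 2, 3 and 4, and 2 to 9 lists, 9 without WT 1. Dclk2 in the inner layer ranged from −0.0283 (reversed, without array 4) to 0.131. Between the layers Dclk2 ranged from −0.0427 (reversed, without animal 5) to 0.116, and Dclk1 from −0.0549 to 0.0441 (reversed, without animal 3).

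Leaving out the arrays high in muscle or bone genes gave 307 genes and 8 lists between the layers, 1346 genes in the inner layer, 1 gene and 1 list in the outer layer and 1 gene shared, and reversed Col1a1 (0.22) and Dclk2 (−0.0462) between the layers. For the inner layer and KO animals that fit holds shifted KO and unshifted WT arrays only. That level as a covariate gave 303 genes and 7 lists between the layers, 1 gene and 1 list in the outer layer, and 1092 genes and 10 lists in KO animals, and reversed Slc4a1 (0.11) and Dclk2 (−0.0179) between the layers.

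With the batch as a term 7 genes were called in the inner layer, 1 in the outer layer, 1 in KO animals and 1 shared, with 7 lists in KO animals, and with an estimated correlation besides 0 lists in the inner layer and 0 in KO animals (5 and 3 at an unadjusted p under 0.05). Within the unshifted arrays limma called 0 genes in each (921, 603 and 283 at an unadjusted p under 0.05) and 7 lists in KO animals. Both fits give a gene the same difference, and reversed were Pgrmc1 (−0.00656) and Dclk2 (−0.18) in the inner layer. In the outer layer these were Abhd17c (−0.28), Bcas2 (−0.38), Kpnb1 (−0.16), Lrrn2 (−0.59), Ptma (−0.10), Rgma (−0.0828), Vps26b (−0.0765) and Zc3h15 (−0.16). In KO animals these were Bcas2 (−0.22), Bok (−0.12), Pgrmc1 (−0.0421), Rgma (−0.13), Vapa (−0.24), Vps26b (−0.0014) and Zc3h15 (−0.21), with the same values in the fit of all arrays with batch. That fit gave 105 genes in the inner layer, 1 in the outer layer and 2 in KO animals, and reversed in the outer layer Abhd17c (−0.14), Bcas2 (−0.0859), Lrrn2 (−0.40), Vapa (−0.15) and Zc3h15 (−0.14).

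Over the named genes, planned settings kept direction and call in 1231 of 1387 values between the layers, 1209 of 1278 in the inner layer, 398 of 593 in the outer layer and 683 of 844 in KO animals. The added fits did so in 153 of 234, 129 of 280, 14 of 130 and 80 of 185. The slide as a block was not run, since the slide is not given in the sources used here, and neither was sex as a covariate, since Xist was below detection on all 15 arrays and Eif2s3y and Kdm5d part them along the batch, so that splitting the arrays by these genes would give the batch term.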

Other observations

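The tests on the WT position between the layers were chosen after the result was seen, and the tests on other splits of the arrays before it.

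Genes of axon guidance and some others differed between the KO layers in both directions, and those named here were chosen after their values were seen. In the outer layer the semaphorin gene Sema3c (0.99 ± 0.12 SE, limma adjusted p = 0.00232), the ephrin receptor gene Ephb1 (0.92 ± 0.13) and Nrp2 (0.73 ± 0.14) were higher. The netrin receptor gene Unc5c (−0.71 ± 0.07), Epha5 (−0.62 ± 0.09), the slit receptor gene Robo1 (−0.60 ± 0.07) and Cntn1 (−0.44 ± 0.08) were lower. Reln, which encodes a secreted migration signal, was lower in the outer layer (−1.17 ± 0.09, adjusted p = 0.000425), and −1.08 in animals 3 and 4. Sema5a (−1.30 ± 0.17) was lower as well, and Rprm was higher (0.90 ± 0.07, adjusted p = 0.000468). Of the newborn neuron markers Neurod1 (0.90 ± 0.15) and Neurog2 (0.80 ± 0.14) were higher, and of the doublecortin family Dclk3 (−0.84 ± 0.10, adjusted p = 0.00193) was lower.

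A hypothesis is that the WT layer may resemble the outer KO layer more than the inner one. On the 307 genes called between the layers in animals 3 and 4, with inner array 5 set to −1 and outer array 5 to 1, the WT arrays lay at 0.224, 0.760, 0.602, 0.583 and 0.536, with a mean of 0.541 and an SD of 0.196 (n = 5). Other scalings and the higher or lower genes alone gave means from 0.522 to 0.588. Single WT arrays lay between 0.135 and 0.859 over these settings, and under median scaling WT 1, 3 and 5 lay nearer to the middle than to the outer array. On the higher genes alone, WT 1 (0.465) and WT 4 (0.478) did so too. The position rests on 1 KO animal, which shares its batch with the WT arrays. Inner array 5, the lower end of the axis, was high in muscle (7.76), bone (7.94) and skin (6.68) transcripts, and outer array 5 was not. WT 1, the highest in muscle transcripts (11.3), lay nearest to the inner end. WT 2 and 3, also high in them, lay at 0.760 and 0.602. Foreign tissue may thus enter the axis, and its part was not tested.

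Other splits of the same arrays bear on whether chance can be excluded. Between the KO layers 1 of 16 splits gave as many genes (1765, and 0 at most in the others) and 1 of 16 as many lists (14, and 13 at most), which are too few splits for a share under 0.05. For the inner layer against WT 1 of 100 gave as many genes (2478, highest other 97) and 11 of 100 as many lists (8, highest other 10). For the outer layer 1 of 100 gave as many genes (1278, highest other 567) and 100 of 100 as many lists (0, highest other 7). For KO animals 1 of 100 gave as many genes (1875, highest other 781) and 40 of 100 as many lists (3, highest other 9). The share of splits was thus under 0.05 for the gene counts of the 3 comparisons with WT and not for their list counts. The splits exchanged shifted and unshifted arrays freely, although KO animals 1 to 4 were shifted and the WT arrays were not. A low share therefore cannot exclude chance apart from the batch, nor does it exclude the batch. The highest other gene counts of the outer layer and of KO animals came from animals 1 to 4 with WT 2 and with WT 1, which follow the batch, and with the batch as a term 1 gene was called in each. For the inner layer the highest came from inner arrays 1, 2 and 5 with WT 1 and WT 3, which were high in muscle transcripts.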
